A study of Mus musculus with 72 samples.

How the data were processed

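Liver total RNA from 72 aged mice was measured on Illumina bead arrays, 1 array per mouse. The labels give a crossed design of strain (C57BL/6J or DBA2/J), sex and diet (food ad libitum, AL, or caloric restriction, CR, of 20% or 40%), with 6 mice in each of the 12 groups. Per the labels, restriction began at 6 months of age, and the livers were taken over 3 days at 23 to 24 months, after 17 to 18 months of diet. On that day CR mice did not receive their ration while AL mice ate until they were killed, so the time since the last meal differed between the diets along with the amount of food.

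Per the labels, RNA was amplified and labelled with the Illumina TotalPrep kit and the arrays were read with GenomeStudio 2011.1. The signal table deposited by the authors holds the probe intensity of every array, without background subtraction or normalization between arrays, as its name and its values show. A detection p-value accompanies each intensity per the file headers. The second table the authors deposited holds a score per probe and sample. Its values equalled, to within 5e-10, the z-score of the log10 intensity within each array for 72 of 72 samples, so it carries no step between arrays and no background correction. This identity was used as a check, not to assign samples. Columns of the signal table are named by strain, sex, diet and an array number, which placed each array in its group. They carry no replicate number, so settings that need the replicate numbers of the labels were run on the authors' z-scores, whose columns carry the sample labels. One sample of the DBA2/J males at 40% CR, replicate 6, is DBA by title and C57BL/J, as spelled there, by its strain entry. It was kept in the group of its title, and the results were recomputed without it. The signal column that holds its values is named for a DBA male at 40% CR. In that group Hc, a gene that differs between the strains, had a mean log2 level of 6.69 (SD 0.22, n = 6), against 9.67 in C57BL/6J males at 40% CR. These values argue for the strain of its title. No sample was left out of the main results.

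Intensities were background-corrected with a normal-exponential model that took its background from the detection p-values, given an offset of 16, normalized by quantiles and log2-transformed (limma 3.58.1 neqc, in R 4.3.3 with statmod 1.5.0 and the package data.table, version 1.17.8). Of 25697 probes on the arrays, 12150 had a detection p-value under 0.01 on at least 6 arrays and were tested. Gene symbols came from the probe table of the series: 23978 probes had 1 symbol, 0 had several and 1719 had none, and 709 of the unnamed probes were among those tested. The symbols were looked up in a table of the assembly GRCm38.p6, used for names alone, which updated 0 of them. The tested probes covered 8441 genes, 2186 of them by several probes. A single fit in limma gave each of the 12 groups a mean and shared the estimate of spread between them. Comparisons were contrasts of those means with moderated statistics, two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 counted as past the threshold. Averages gave the 4 strain-sex groups (for diet) or the 6 groups of the other factors (for sex and strain) equal weight. Every adjusted p-value of a gene below comes from this limma fit, and every error is a standard error (SE) unless called an SD. The number of arrays, 6 per group, limits the precision of each value.

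A probe that was above background on no array of a group has no ratio there. In that case the dimmer group was set, on each of its arrays, to the lowest normalized value of any detected probe or to its own value if higher, and the ratio is given as "at least N-fold". In an average this was done for each such group on the dimmer side. No bound is given where this left no difference. Changes given on the log2 scale are the fitted values, also near background.

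The 40 gene lists comprised 27 pathways, 11 sets of cell type markers and 2 control sets, with 944 genes of which 832 were named on the arrays and 706 tested. None was chosen by the study or on these arrays. Each list was compared with all other genes by camera in limma with an inter-gene correlation preset at 0.01, on 1 probe per gene (the brightest), with p-values adjusted over the 40 lists of a comparison. The same test with a correlation estimated for each list was run as an alternative. Counts of a list's members past the threshold use the p-values adjusted over all tested probes, and a second count uses p-values adjusted over the list alone. A list's score is the mean log2 level of its members on an array.

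Named genes followed a rule. For the averages of 40% CR, 20% CR, sex and strain it took the 6 largest rises and 6 largest falls past the threshold that had the same sign in every group averaged. It added, for up to 6 lists with the lowest adjusted p-values, the 3 members with the largest moderated statistics. For 40% against 20% CR it took 3 rises and 3 falls, for each difference of effects 4 of each sign, and for each strain-sex group at 40% CR 3 of each. Unnamed probes and genes known only by clone or predicted-gene numbers were skipped. Xist, Ddx3y, Eif2s3y and Kdm5d (sex) and Nnt, Gpnmb, Hc and Glo1 (strain) were set to be named as checks of the labels, but no tested probe carried the name Ddx3y. The groups, comparisons, tests, lists, rule and alternative settings below were set, except where stated otherwise, before the data were examined.

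The steps were tested on simulated data with the same 12 groups and 12150 probes, over 5 simulations. For the average of 40% CR against AL, 76% of probes changed 1.25-fold were called, 96.4% of those changed 1.5-fold, 99.2% at 2-fold and 100% at 4-fold, with 0.06% of unchanged probes called. For 40% CR in C57BL/6J females alone the shares were 16.8%, 69.6%, 94.4% and 100%, with 0.07% of unchanged probes. In the same simulations, where genes varied independently, a list shifted by 0.3 was called in 5 of 5 and other lists in 0. In the real data, where genes vary together, random splits of the arrays had a median of 8 to 10 of 40 lists past the threshold.

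The alternative settings were quantile normalization without background correction, the authors' z-scores, no detection filter, probes detected on all 72 arrays only, an intensity trend with a robust prior, array weights, the replicate number as a block, the fit of only the 12 arrays of 2 groups, the sample with 2 strain entries left out, each array left out in turn, and the estimated correlation for lists. The files do not name the slides, so a block for slides was not run. Runs of 8 columns in the signal table took its place, and 4 arrays that stood apart in correlation with their group were left out together. Both settings were added after the data were seen, as was the use of z-scores for the replicate block and for leaving out the sample with 2 strain entries. Overlap of the 20% and 40% CR effects was compared with 100 simulations of unchanged groups that shared the AL arrays. Other splits of the arrays into groups of the same sizes were counted, 100 per comparison with the real one included. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.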

Results

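The data are liver expression levels from 72 mice, 6 in each of 12 groups that cross strain (DBA2/J or C57BL/6J), sex and diet (AL, 20% CR or 40% CR). Between 32.3% and 44.95% of the probes on an array were above background at a detection p-value under 0.01, and 6362 probes were above it on all 72 arrays. The mean raw signal of an array ranged from 136 to 308. The mean share of probes above background was lowest in DBA2/J males at 20% CR (33.7% ± 1.31, SD, n = 6) and highest in C57BL/6J males at 40% CR (40.6% ± 1.23, SD, n = 6). The first principal component held 29.5% of the variance, and strain accounted for 90.2% of its spread. The second held 18.7%, of which diet accounted for 76%, and the third held 8.9%, of which sex accounted for 62.9%.

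**Figure D1:**
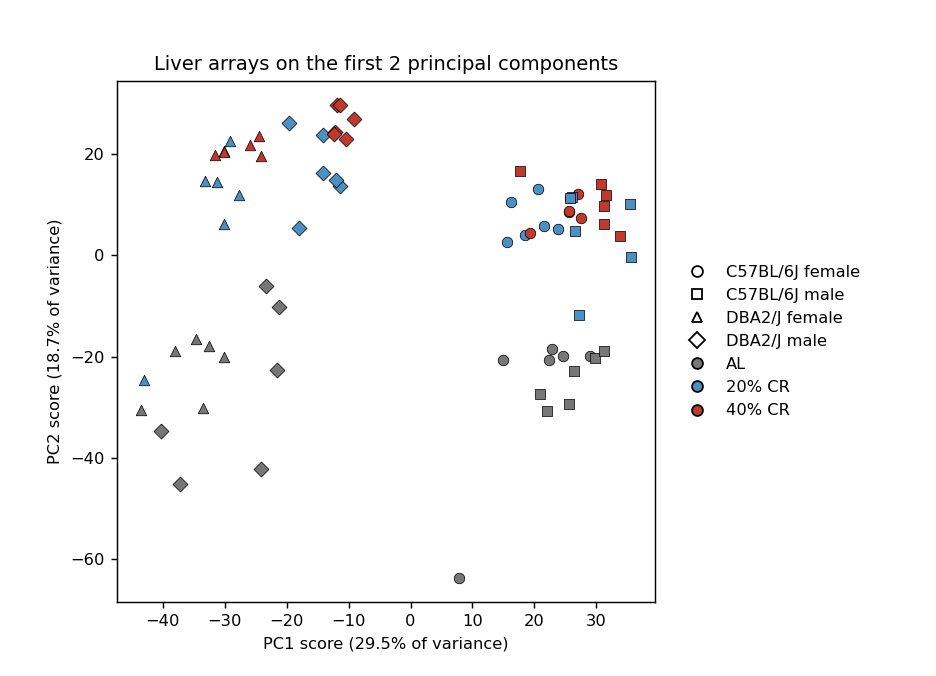
Scores of the 72 arrays on the first principal component (x axis, 29.5% of variance) and the second (y axis, 18.7%), with colour for diet and marker shape for strain and sex. DBA2/J and C57BL/6J arrays separate along the x axis. AL arrays lie mostly below CR arrays on the y axis, with some overlap.

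The first comparison asks what 40% CR changed in the aged liver, averaged over both strains and sexes (24 mice against 24). Cyp4a14, a fatty acid omega-hydroxylase controlled by the nuclear receptor PPARα, rose 28.8-fold (log2 4.85 ± 0.30, adjusted p = 1.08e-21), by 3.29 to 6.09 on the log2 scale in the 4 strain-sex groups. The acyl-CoA thioesterases Acot3 (9.55-fold, log2 3.26 ± 0.30) and Acot1 (7.17-fold, log2 2.84 ± 0.29) rose with it. So did Dbp, a clock-output transcription factor (10.3-fold, log2 3.37 ± 0.16, adjusted p = 6.58e-27), and the ubiquitin protease Usp2 (8.1-fold, log2 3.02 ± 0.11, adjusted p = 5.7e-34). The cytochrome P450 Cyp2b13 rose 10.9-fold (log2 3.44 ± 0.33), from 1.15 in the group that changed least to 5.12 on the log2 scale. Falls were largest for the major urinary proteins Mup2 (24.2-fold, log2 -4.60 ± 0.37, adjusted p = 6.97e-17) and Mup6 (17.6-fold, log2 -4.14 ± 0.33). Also lower were the water channel Aqp8 (7.42-fold, log2 -2.89 ± 0.21), the extracellular matrix protein Spon2 (6.56-fold, log2 -2.71 ± 0.14), the glycosyltransferase Ugt3a1 (4.91-fold, log2 -2.30 ± 0.16) and Mup20 (at least 3.75-fold). As the rule for naming required, all 12 genes had the same sign in 4 of 4 strain-sex groups, although the mean change of Mup20 in 1 of them was only -0.02. It was above background on 5 of 24 CR arrays and 17 of 24 AL arrays. In all, 6875 probes of 12150 (56.6%) passed the threshold, 3659 up and 3216 down. Of these 528 rose and 716 fell at least 1.5-fold. Of the 6875, 4970 (72.3%) had the same sign in all 4 groups. Among the 6362 probes above background on all 72 arrays, 4148 passed.

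Genes of fuel use rose together. In the list of fatty acid oxidation and PPARα targets 27 of 30 measured genes rose and 0 fell (list adjusted p = 6.97e-12, median log2 change 0.82). Among them were Cyp4a31 (6.84-fold, log2 2.77 ± 0.21) and the enoyl-CoA isomerase Eci2 (2.28-fold, log2 1.19 ± 0.08). That list had adjusted p = 0.254 with an estimated correlation. Of 66 oxidative phosphorylation genes 49 rose and 3 fell (50 and 4 adjusted over the list alone, list adjusted p = 1.85e-10, median 0.28, adjusted p = 0.328 with an estimated correlation). The ATP synthase subunit Atp5a1 rose 2.15-fold, complex I subunit Ndufv1 1.51-fold and complex IV subunit Cox4i1 1.4-fold. For each list with no second count, the count adjusted over the list alone equalled the first. The list of urea cycle and amino acid catabolism genes had 19 of 26 up and 2 down (list adjusted p = 4.78e-05, adjusted p = 0.398 with an estimated correlation). Alanine aminotransferase Gpt rose 2.12-fold, tryptophan dioxygenase Tdo2 at least 1.93-fold and proline dehydrogenase Prodh 1.9-fold. Of 14 gluconeogenesis and fasting genes 11 rose and 0 fell (list adjusted p = 0.000888, adjusted p = 0.254 with an estimated correlation). Pck1, the enzyme that commits carbon to glucose synthesis, rose by 1.44 ± 0.11 on the log2 scale, and the coactivator Ppargc1a by 1.31 ± 0.16, both chosen after their values were seen. The circadian clock list had 11 of 17 up and 3 down (list adjusted p = 4.78e-05, adjusted p = 0.0786 with an estimated correlation). The clock-output factor Tef rose 4.56-fold (log2 2.19 ± 0.10), and Per2 by 1.94 ± 0.11, while Npas2 fell by 0.42 (SE 0.05), the last 2 chosen after their values were seen. The time since the last meal also differed between AL and CR mice. These and the other changes from AL to CR therefore cannot be assigned to the amount of food alone.

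Lipid and sterol synthesis fell. Of 19 lipogenesis genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, list adjusted p = 0.00196, adjusted p = 0.401 with an estimated correlation). Of 18 cholesterol synthesis genes 12 fell and 0 rose (list adjusted p = 0.00295, adjusted p = 0.401 with an estimated correlation). Chosen after their values were seen, the lipogenic transcription factor Srebf1 changed by -1.32 ± 0.15, Acly by -1.05 ± 0.13 and the sterol synthesis enzyme Hmgcs1 by -1.19 ± 0.15. The endoplasmic reticulum stress list had 13 of 23 down and 4 up (14 and 4 adjusted over the list alone, list adjusted p = 0.000922, adjusted p = 0.328 with an estimated correlation). The chaperone Calr, at -1.23 ± 0.11, was chosen after its value was seen. Proteasome subunits were down in 17 of 27 and up in 1 (list adjusted p = 0.00332, median -0.16, adjusted p = 0.398 with an estimated correlation). Ribosomal proteins were up in 20 of 52 and down in 3 (19 and 3 adjusted over the list alone, list adjusted p = 0.0486, median 0.089, adjusted p = 0.662 with an estimated correlation). Of 17 cell cycle genes 13 fell and 0 rose (list adjusted p = 0.0038, adjusted p = 0.401 with an estimated correlation). The replication factor Mcm5, at -0.98 ± 0.18, was chosen after its value was seen. In cytochrome P450 families 1 to 3, 20 of 28 genes rose and 4 fell (list adjusted p = 0.000876, adjusted p = 0.328 with an estimated correlation). Cyp2a5 (1.73 ± 0.16) and Cyp2f2 (-1.04 ± 0.12) mark both directions and were chosen after their values were seen.

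Immune genes fell. All 21 measured interferon response genes fell (list adjusted p = 6.06e-10, median -0.93, adjusted p = 0.254 with an estimated correlation). They included the interferon-induced Isg15 (3.3-fold, log2 -1.72 ± 0.16), Oasl1 (2.61-fold) and Dhx58 (2.54-fold). Of 21 antigen presentation genes 15 fell and 1 rose (list adjusted p = 0.000876, adjusted p = 0.401 with an estimated correlation), with the class II genes H2-Eb1 at -1.53 ± 0.33 and H2-Ab1 at -1.35 ± 0.29. Of 25 acute phase genes 13 fell and 1 rose (list adjusted p = 0.0105, adjusted p = 0.47 with an estimated correlation), with serum amyloid Saa1 at -1.97 ± 0.38. Markers of immune cells moved with these groups. Of the Kupffer cell and macrophage markers 13 of 16 fell and 1 rose (list adjusted p = 0.00223, adjusted p = 0.401 with an estimated correlation). The Kupffer cell lectin Clec4f changed by -1.04 ± 0.13 and the scavenger receptor Cd163 the other way, by 1.55 ± 0.21. Neutrophil markers fell in 7 of 11 (list adjusted p = 0.0207, adjusted p = 0.47 with an estimated correlation), with Ltf at -1.80 ± 0.32. B and plasma cell markers fell in 5 of 6 (6 adjusted over the list alone, list adjusted p = 0.0323, adjusted p = 0.401 with an estimated correlation), with Cd79b at -1.09 ± 0.21. Erythroid markers fell in 4 of 4 (list adjusted p = 0.0486, adjusted p = 0.398 with an estimated correlation), with Alas2 at -1.03 ± 0.15. T and NK cell markers fell in 9 of 12 and rose in 1, but the list did not pass (adjusted p = 0.0595). The 8 single genes in this paragraph other than the interferon genes were chosen after their values were seen. One array of the C57BL/6J AL females, array 5, stood above the other 5 of its group by 3.82 (log2) in the mean of the neutrophil markers and 2.75 in the B cell markers. Without it and 3 more arrays that stood apart, the interferon list had adjusted p = 5.48e-10, the Kupffer cell list 0.00267 and the neutrophil list 0.0478, and the erythroid list no longer passed (0.0597). The DBA2/J AL males were split as well, with a mean of the B cell markers of 6.47 on arrays 3, 4 and 13 and 4.46 on the other 3, and of the antigen presentation genes of 8.73 and 7.04. Without these 3 and the 4, a setting chosen after the data were seen, the mean of the antigen presentation genes changed by -0.29 ± 0.08 rather than -0.59 ± 0.14, that of the B cell markers by -0.47 ± 0.07 rather than -0.80 ± 0.17, and the neutrophil list did not pass (0.0693).

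**Figure D2:**
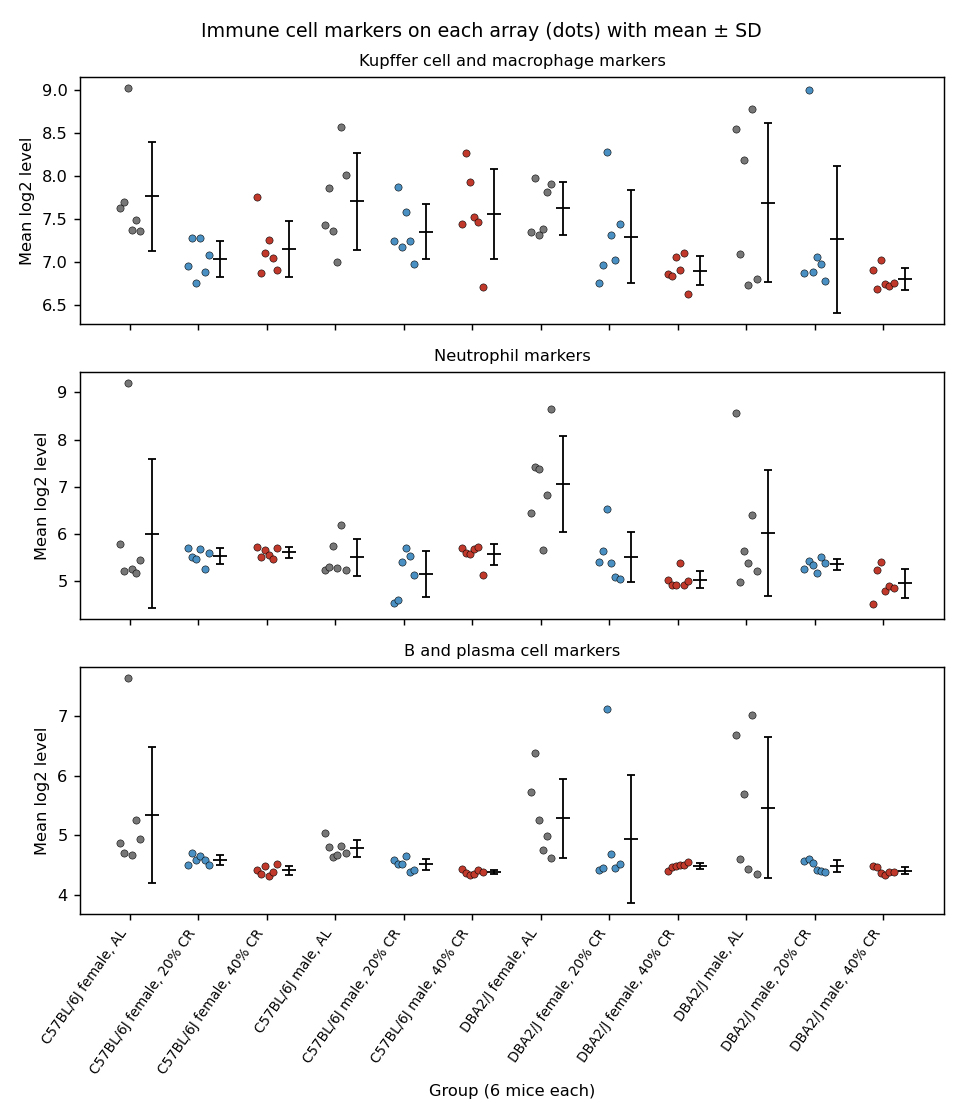
Mean log2 level of the Kupffer cell, neutrophil and B and plasma cell markers (y axis) on each array (dots), with mean and SD, in the 12 groups of 6 mice (x axis). Over the 4 strain-sex groups the means changed by -0.59 ± 0.15, -0.86 ± 0.21 and -0.80 ± 0.17 (SE) from AL to 40% CR, and array 5 of the C57BL/6J AL females lies at 9.19 for neutrophil markers, against 5.79 for the next array. Array 4 of the DBA2/J AL females lies at 8.64, against a mean of 6.74 for the other 5.

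Among the structural cell types, stellate cell and fibroblast markers fell in 7 of 15 and rose in 2 (9 and 2 adjusted over the list alone, list adjusted p = 0.00584, adjusted p = 0.398 with an estimated correlation), with the basement membrane collagen Col4a1 at -1.05 ± 0.12. Endothelial markers were down in 8 of 15 and up in 1 (9 and 1 adjusted over the list alone), but the list did not pass (adjusted p = 0.0561). Hepatocyte markers rose in 7 of 12 and fell in 0 (list adjusted p = 0.0323, median 0.12, adjusted p = 0.328 with an estimated correlation), with the retinol carrier Rbp4 at 1.53 ± 0.08. Bile duct (cholangiocyte) markers had 1 of 5 up and 1 down (adjusted p = 0.655), adipocyte markers 1 of 3 up and 1 down (adjusted p = 0.637) and markers of the exocrine pancreas 1 of 4 up and 2 down (adjusted p = 0.911). In the last 2 lists the median was negative (-0.032 and -0.16) while the mean was positive (0.12 and 0.022) and the test upward. Plin4, which coats lipid droplets, stood at 2.15 ± 0.19 in the adipocyte list, Car3 at -1.76 ± 0.41. The 4 genes in this paragraph were chosen after their values were seen.

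Genes of the male liver fell. Of 22 male-biased liver genes 19 fell and 1 rose (19 and 2 adjusted over the list alone, list adjusted p = 1.58e-07, median -1.08, adjusted p = 0.254 with an estimated correlation). Among them were Mup2, the complement component C6 (3.1-fold, log2 -1.63 ± 0.15) and the oxysterol hydroxylase Cyp7b1 (2.77-fold, log2 -1.47 ± 0.14). The female-biased list had 7 of 11 up and 3 down and did not pass (adjusted p = 0.083). The control list of 4 strain marker genes fell too, in 4 of 4 (list adjusted p = 0.0428, adjusted p = 0.254 with an estimated correlation). Its genes were Gpnmb at -0.62 ± 0.17, Glo1 at -0.45 ± 0.06, Hc at -0.23 ± 0.08 and Klrd1 at -0.21 ± 0.05.

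**Figure D3:**
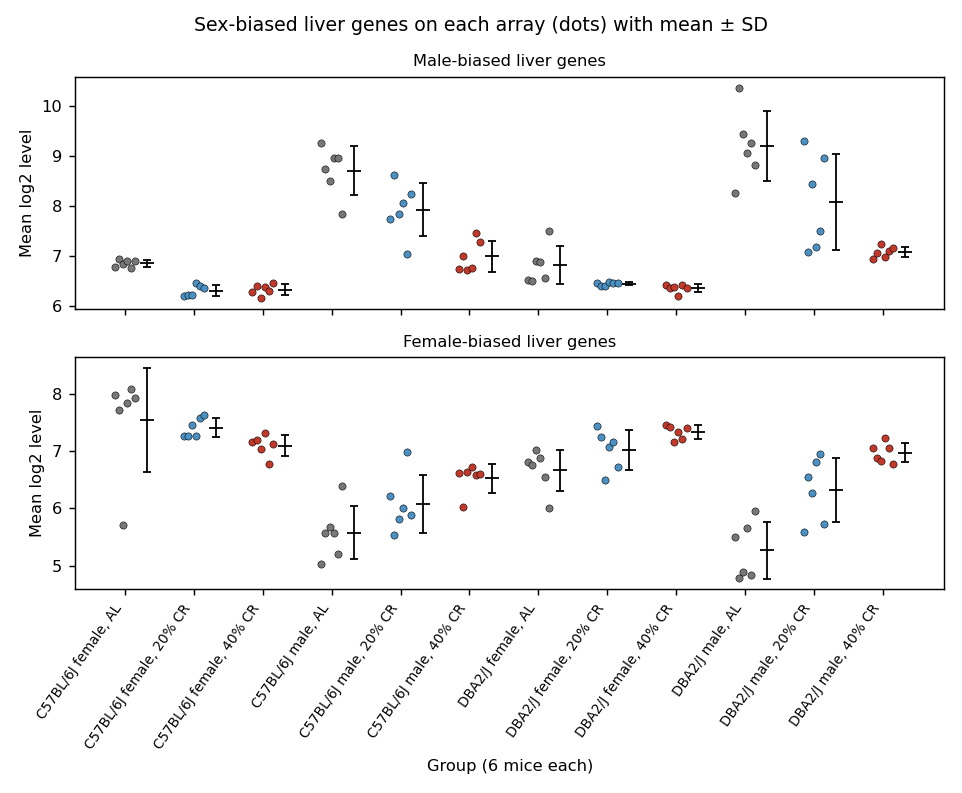
Mean log2 level of the male-biased and female-biased liver gene lists (y axis) on each array (dots), with mean and SD, in the 12 groups of 6 mice (x axis). The male-biased mean of DBA2/J males was 9.21 under AL, 8.08 at 20% CR and 7.08 at 40% CR, against 6.81 in DBA2/J AL females.

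Of the 40 lists, 23 passed at 40% CR, 0 of them with an estimated correlation. A list adjusted p under 0.05 is weak evidence, as other splits of the same arrays had a median of 10 lists past the threshold. Such splits mix AL and CR arrays and can keep part of a diet effect, so this median is not a rate without any effect. The 23 had the same direction under quantile normalization and with the authors' z-scores. There B cell (adjusted p = 0.057 and 0.0595) and erythroid markers (0.0542 and 0.0685) no longer passed. Hepatocyte markers (0.0811) and the strain marker list (0.0675) did not pass on the z-scores.

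**Figure D4:**
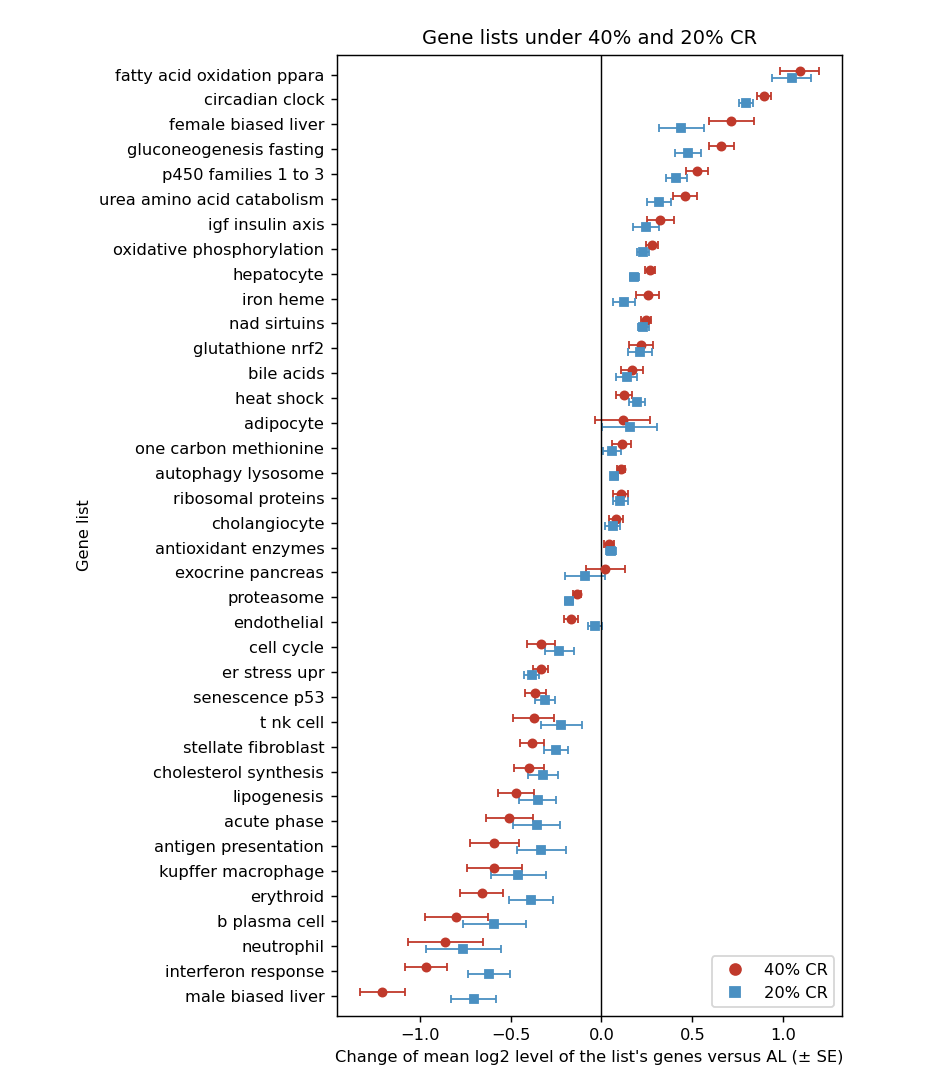
Change in the mean log2 level of the genes of 38 lists (y axis) at 40% and 20% CR relative to AL (x axis, log2), averaged over the 4 strain-sex groups of 6 mice per diet, with SE bars. The fatty acid oxidation mean rose by 1.09 ± 0.11 at 40% CR, and the interferon mean changed by -0.97 ± 0.12.

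The milder restriction, 20% CR against AL (24 mice against 24), moved many of the same genes. Cyp4a14 rose 16.3-fold (log2 4.03 ± 0.30, adjusted p = 7.07e-18), Dbp 9.93-fold (log2 3.31 ± 0.16), Usp2 8.49-fold (log2 3.09 ± 0.11), Acot3 7.63-fold, Cyp4a31 6.09-fold and Acot1 5.4-fold. Spon2 fell 6.35-fold (log2 -2.67 ± 0.14, adjusted p = 1.62e-24), Aqp8 6.22-fold, Mup2 6.2-fold (log2 -2.63 ± 0.37) and Mup6 6-fold. Also down were the neutrophil serine protease Prtn3 3.86-fold (log2 -1.95 ± 0.27) and the magnesium transporter Slc41a2 3.07-fold (log2 -1.62 ± 0.15). By the rule for naming, all 12 had the same sign in 4 of 4 strain-sex groups. The threshold was passed by 5916 probes (48.7%), 3066 up and 2850 down, of which 375 rose and 479 fell at least 1.5-fold. Of them 4096 (69.2%) had the same sign in all 4 groups. Of the 6362 probes above background on all arrays, 3737 passed.

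By list, 29 of 30 fatty acid oxidation genes rose and 0 fell (list adjusted p = 1.1e-16, adjusted p = 0.251 with an estimated correlation), with Eci2 up 2.1-fold. Oxidative phosphorylation had 52 of 66 up and 0 down (53 and 0 adjusted over the list alone, list adjusted p = 5.49e-12, adjusted p = 0.304 with an estimated correlation). Atp5a1 was up 1.61-fold in the average although 1 of the 4 groups was at -0.02, and the complex I subunits Ndufs7 and Ndufs3 rose 1.34-fold and 1.26-fold. The interferon list had 18 of 21 down and 0 up (19 and 0 adjusted over the list alone, list adjusted p = 4e-06, adjusted p = 0.417 with an estimated correlation). Oasl1 fell 2.46-fold, Isg15 2.31-fold and Dhx58 2.28-fold. Endoplasmic reticulum stress genes fell in 14 of 23 and rose in 1 (list adjusted p = 9.88e-06, adjusted p = 0.251 with an estimated correlation). These included Creld2 (2.32-fold) and the protein disulfide isomerases Pdia4 (1.9-fold) and Pdia3 (1.65-fold). The clock list had 9 of 17 up and 3 down (list adjusted p = 3.56e-05, adjusted p = 0.0632 with an estimated correlation), with Tef up 4.21-fold. Proteasome subunits fell in 17 of 27 (list adjusted p = 0.00013, adjusted p = 0.304 with an estimated correlation), with Psmc2 down 1.34-fold, Psma5 1.32-fold and Psmd7 1.31-fold.

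Male-biased genes fell in 17 of 22 and rose in 1 (list adjusted p = 0.00042, adjusted p = 0.423 with an estimated correlation). Cytochrome P450 genes rose in 20 of 28 and fell in 4 (0.000516, adjusted p = 0.361 with an estimated correlation), and gluconeogenesis genes rose in 11 of 14 (0.00163, adjusted p = 0.304 with an estimated correlation). Urea cycle and amino acid genes rose in 14 of 26 and fell in 1 (15 and 1 adjusted over the list alone, 0.000711, adjusted p = 0.531 with an estimated correlation). A further 6 lists passed downward, each with adjusted p = 0.531 with an estimated correlation. They were lipogenesis (12 of 19 down, 1 up, 0.0101), cholesterol synthesis (9 of 18 down, 0.013), Kupffer cell markers (12 of 16 down, 1 up, 13 and 1 adjusted over the list alone, 0.0105) and neutrophil markers (7 of 11 down, 0.0258). Acute phase genes (12 of 25 down, 1 up, 0.0258) and cell cycle genes (10 of 17 down, 1 up, 12 and 1 adjusted over the list alone, 0.027) were the others. Ribosomal proteins (19 of 52 up, 3 down, 18 and 2 adjusted over the list alone, 0.013) and heat shock genes (9 of 14 up, 1 down, 0.0258) passed upward, with adjusted p = 0.575 and 0.485 with an estimated correlation. These 18 lists had the same direction under both other scalings, but on the z-scores acute phase (adjusted p = 0.129) and cell cycle genes (0.062) no longer passed, and acute phase genes did not without the 4 arrays that stood apart (0.0819). One of the 4, array 64 of the DBA2/J females at 20% CR, lay above the other 5 of its group by 2.62 (log2) in the mean of the B cell markers and by 1.42 in that of the interferon genes. On the AL side, array 5 of the C57BL/6J females, array 4 of the DBA2/J females and 3 DBA2/J males had high neutrophil markers. Without the 4 arrays the neutrophil mean changed by -0.57 ± 0.15 rather than -0.76 ± 0.21, and the Kupffer cell mean by -0.43 ± 0.14 rather than -0.46 ± 0.15. Chance could not be excluded for the number of lists, since 11 of 100 splits of the arrays, the real one included, gave at least 18.

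Going from 20% to 40% CR separated the diets less. Cyp2b13 was 2.72-fold higher at 40% CR (log2 1.45 ± 0.33, adjusted p = 0.00164), the transporter Slc22a26 1.77-fold (log2 0.82 ± 0.23) and the insulin-like growth factor binding protein Igfbp1 1.72-fold (log2 0.78 ± 0.20). Mup2 was 3.9-fold lower (log2 -1.96 ± 0.37, adjusted p = 0.000219), Mup6 2.94-fold lower (log2 -1.56 ± 0.33) and Ugt3a1 2.28-fold lower (log2 -1.19 ± 0.16, adjusted p = 2.56e-06). Male-biased genes fell further in 11 of 22 (list adjusted p = 3.11e-07, adjusted p = 0.555 with an estimated correlation), such as Gstp2 at -0.98 ± 0.16. Interferon genes fell further in 8 of 21 (12 adjusted over the list alone, list adjusted p = 6.23e-07, adjusted p = 0.877 with an estimated correlation), such as Ifit3 at -0.87 ± 0.19. Antigen presentation genes fell in 4 of 21 (0.000403, adjusted p = 0.877 with an estimated correlation). Array 64 of the DBA2/J females at 20% CR raised the 20% CR side of both lists. Without the 4 arrays the mean of the antigen presentation genes changed by -0.16 ± 0.11 rather than -0.26 ± 0.14 (list adjusted p = 0.0185) and that of the interferon genes by -0.27 ± 0.11 rather than -0.35 ± 0.12 (3.75e-05). Endothelial markers fell in 6 of 15 (7 adjusted over the list alone, 0.000772, adjusted p = 0.378 with an estimated correlation), with Fcgr2b at -0.41 ± 0.09. Stellate cell markers fell in 3 of 15 (3 down and 1 up adjusted over the list alone, 0.0265, adjusted p = 0.877 with an estimated correlation). Urea cycle and amino acid genes rose in 5 of 26 (6 adjusted over the list alone, 0.013, adjusted p = 0.877 with an estimated correlation), with Tdo2 at 0.46 ± 0.10. Of the fatty acid oxidation genes 1 rose and 1 fell, and that list had a median of 0.018, a test in the downward direction and adjusted p = 0.906. Gstp2, Ifit3, Fcgr2b and Tdo2 were chosen here after their values were seen. Of 1725 probes past the threshold (14.2%), 1094 were up and 631 down, and 10 rose and 33 fell at least 1.5-fold. The stellate cell list no longer passed under quantile normalization (0.051) or without the 4 arrays (0.0865), nor the urea cycle list on the z-scores (0.0802). At least 6 lists came from 72 of 100 splits, so chance could not be excluded for that number.

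Across the 12150 probes, which are not independent replicates, the changes at 20% and 40% CR had r = 0.93 (Spearman's rho 0.888, covariance 0.127). Both were measured against the same AL mice, which alone gave r = 0.498 on average in 100 simulations without any effect, but a covariance of 0.00346 and 0 shared calls. Probes varied independently in these simulations, unlike on the real arrays, so 0 shared calls may be too low a baseline. Of the calls, 4931 were shared in the same direction (2550 up and 2381 down) and 8 in opposite directions, where independent sets of these sizes would share 923 up and 754 down. With separate AL mice for each diet, split by column number, 3683 were shared (r = 0.888, 5 opposite), and with AL replicates 1 to 3 and 4 to 6 on the authors' z-scores 3138 were shared (r = 0.836, 76 opposite).

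The strains and sexes each responded to 40% CR. In C57BL/6J females Cyp4a14 rose 23.6-fold (log2 4.56 ± 0.60), Cyp4a31 10.7-fold and Cyp2d9 10.2-fold, while Mup2 fell most, with a log2 change of -7.01 ± 0.74 (adjusted p = 7.17e-11), ahead of Mup6 (77.6-fold) and A1bg (38.8-fold). In C57BL/6J males Cyp2b13 rose 19.5-fold (log2 4.29 ± 0.65), Acot3 12.9-fold and Usp2 10.7-fold, while Mup2 fell 82.5-fold, Serpina1e, an alpha-1-antitrypsin, 56.7-fold and Mup6 43.2-fold. DBA2/J females showed rises of Cyp4a14 (68.3-fold), Acot1 (24.2-fold) and the pyruvate dehydrogenase kinase Pdk4 (23.6-fold), with falls of the neutrophil granule protein Ltf (at least 9.55-fold lower), Spon2 (10.2-fold) and the neutrophil protein S100a8 (8.95-fold). The AL mice of that group include array 4, whose mean of the neutrophil markers lay 1.90 (log2) above that of the other 5. DBA2/J males showed rises of Cyp4a14 (43.9-fold), Cyp2b13 (34.8-fold) and Dbp (18.8-fold), with falls of the glutathione transferase Gstp2 (33-fold), the male-biased P450 Cyp4a12a (27.2-fold) and Mup21 (17.1-fold). Each fold is from 6 mice against 6.

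By count, 2821 probes passed in C57BL/6J females (1562 up), 3171 in C57BL/6J males (1768 up), 3725 in DBA2/J females (2023 up) and 5204 in DBA2/J males (2757 up). At 20% CR the counts were 3115 (1742 up), 2033 (1064 up), 2461 (1287 up) and 4479 (2261 up). In C57BL/6J females 55.4% of calls were up at 40% CR and 55.9% at 20% CR, but 40.7% and 42.4% on the authors' z-scores. Fatty acid oxidation genes rose in 19 of 30 in C57BL/6J females (24 adjusted over the list alone, list adjusted p = 3.24e-12, adjusted p = 0.425 with an estimated correlation). Their AL mice include array 5, whose mean of these genes was 7.10 against 8.63 for the other 5, which adds to the rise (list adjusted p = 2.47e-08 without the 4 arrays). In C57BL/6J males 13 rose and 2 fell (0.00329, adjusted p = 0.774 with an estimated correlation). The list had 26 up in DBA2/J females (28 adjusted over the list alone, 2.71e-18, adjusted p = 0.186 with an estimated correlation) and 21 in DBA2/J males (22 adjusted over the list alone, 6.32e-08, adjusted p = 0.348 with an estimated correlation). The clock list held with an estimated correlation in DBA2/J females (10 up, 2 down, list adjusted p = 1.84e-05, adjusted p = 0.0469 with an estimated correlation) and DBA2/J males (11 up, 3 down, 2.62e-06, adjusted p = 0.0214 with an estimated correlation). Neutrophil markers fell in 10 of 11 in DBA2/J females (8.88e-06, adjusted p = 0.417 with an estimated correlation), where array 4 raised the AL mean (8.84e-06 without the 4 arrays). With only the 12 arrays of the comparison, C57BL/6J females had 1855 calls. With runs of 8 columns fitted as a block (a stand-in for slides chosen after the data were seen) C57BL/6J males had 702 and DBA2/J females 1521 at 40% CR (with Cyp2b13 and Acot3 in the males at 2.56 and 3.40 and S100a8 in the females at -2.81 no longer past the threshold). At 20% CR C57BL/6J females had 724, C57BL/6J males 1192 and DBA2/J females 1536. The runs largely overlap with the groups, so these lower counts neither show nor exclude an effect of slides. Of the probes above background on all arrays, 3117 passed in DBA2/J males at 40% CR and 2730 at 20% CR.

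**Figure D5:**
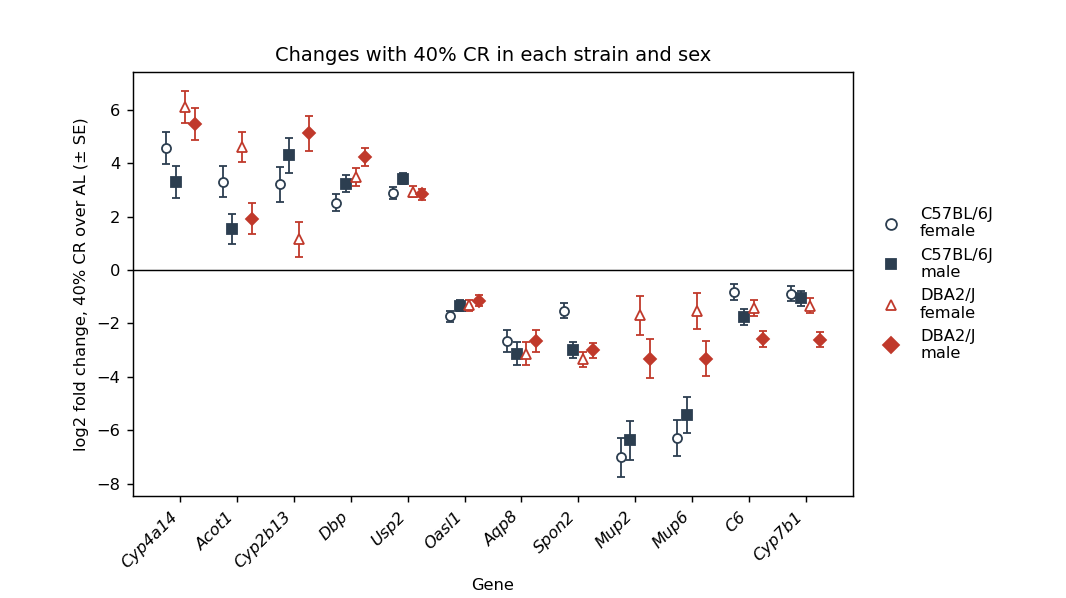
Change from AL to 40% CR (y axis, log2 fold change with SE bars) of 12 genes in each strain-sex group of 6 mice per diet (x axis). Cyp4a14 rose by 3.29 to 6.09 and Mup2 changed by -7.01 to -1.70, while Aqp8 stayed between -3.13 and -2.65.

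The sex comparison asks which genes differ between males and females (36 mice against 36, averaged over strains and diets). The P450s Cyp4a12a (at least 10.1-fold, adjusted p = 8.68e-20, above background in 35 of 36 males and 2 of 36 females) and Cyp2d9 (11.5-fold, log2 3.53 ± 0.15), Mup2 (10.7-fold, log2 3.42 ± 0.30), Mup6 (7.19-fold) and Gstp2 (5-fold) were higher in males, as was the Y-linked Eif2s3y (at least 5.02-fold, above background in 36 of 36 males and 0 of 36 females). Females had more Cyp2b13 (5.91-fold, log2 -2.56 ± 0.27, adjusted p = 2.04e-12), the steroid hydroxylase Cyp17a1 (3.86-fold), A1bg (at least 3.19-fold, above background in 22 of 36 females and 3 of 36 males), Slc22a26 (3.63-fold), Cyp2b23 (3.24-fold) and the nucleotidase Nt5e (3.11-fold, log2 -1.64 ± 0.12). By the rule for naming, each had the same sign in 6 of 6 strain-diet groups, although A1bg differed by only -0.01 in 1 of them. Of 5146 probes past the threshold (42.4%), 2490 were higher and 2656 lower in males. Of these 378 differed at least 1.5-fold, 251 of them higher in males, and 2063 (40.1%) had the same sign in all 6 groups. Of the probes above background on all arrays, 2976 passed. Xist, the X-inactivation RNA, was above background in 36 of 36 females and 0 of 36 males (at least 1.83-fold lower in males). The Y-linked Kdm5d was above background in 9 of 36 males and 0 of 36 females, which left no ratio. Uty, another Y-linked gene, chosen after its values were seen, was above background in 15 of 36 males and 4 of 36 females. Within groups 1156, 1593 and 644 probes differed by sex in C57BL/6J mice under AL, 20% and 40% CR, and 737, 4005 and 2937 in DBA2/J mice.

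The male-biased list was higher in males in 19 of 22 genes and lower in 0 (20 and 0 adjusted over the list alone, list adjusted p = 1.95e-20), with Cyp7b1 at 4-fold, and passed with an estimated correlation (adjusted p = 0.0147). Of 11 female-biased genes 8 were lower in males and 1 higher (list adjusted p = 0.000224, adjusted p = 0.18 with an estimated correlation), with the hydroxyacid oxidase Hao2 at least 1.51-fold lower. Stellate cell markers were lower in males in 11 of 15 (0.00161, adjusted p = 0.47 with an estimated correlation), with Lrat (above background in 15 of 36 males and 25 of 36 females), Rgs5 (1.51-fold) and Mgp (1.46-fold). Endothelial markers were lower in 8 of 15 (0.0327, adjusted p = 0.519 with an estimated correlation). Acute phase genes were lower in 15 of 25 and higher in 1 (0.00307, adjusted p = 0.638 with an estimated correlation). The chemokine Cxcl1 was 4.43-fold lower (5 of 6 groups), metallothionein Mt1 1.82-fold and Stat3 1.59-fold. Higher in males were glutathione and Nrf2 genes in 15 of 27 (15 up and 1 down adjusted over the list alone, 0.00337, adjusted p = 0.638 with an estimated correlation). Gstp1 was at 2.07-fold, Gsta2 at 2.03-fold (5 of 6 groups) and Gstm1 at 1.45-fold. Oxidative phosphorylation genes went both ways, 23 of 66 up and 12 down (24 and 13 adjusted over the list alone, 0.0071, median 0.042, adjusted p = 0.757 with an estimated correlation). Ndufb9 was 2.16-fold, Atp5a1 2.14-fold and Sdhd 2.09-fold higher in males. Proteasome subunits (13 of 27 up, 2 down, 0.0071, adjusted p = 0.638 with an estimated correlation) and hepatocyte markers (7 of 12 up, 1 down, 0.00858, adjusted p = 0.301 with an estimated correlation) were higher. Senescence and p53 genes were lower in 7 of 13 (0.0172, adjusted p = 0.302 with an estimated correlation). The 10 lists had the same direction under both other scalings, where acute phase genes no longer passed on the z-scores (0.069), and endothelial markers did not pass without the 4 arrays (0.0662). Chance could not be excluded for the number of lists, since 44 of 100 splits gave at least 10.

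Strain gave the largest number of calls (36 mice against 36). DBA2/J mice had more of the class II gene H2-Ea (at least 16.8-fold, above background in 36 of 36 DBA2/J and 0 of 36 C57BL/6J mice), Rassf4 (18.8-fold, log2 4.23 ± 0.08, with 3 other probes in the same direction), the thiopurine methyltransferase Tpmt (18.6-fold, log2 4.21 ± 0.07), H2-K1 (11.9-fold), Dnaic1 (at least 11-fold) and H2-Q5 (at least 9.98-fold). A second H2-K1 probe was called in the opposite direction. Lower in DBA2/J were Haao of tryptophan breakdown (at least 58.6-fold, adjusted p = 1.52e-60, above background in 16 of 36 DBA2/J mice), the proteasome subunit Psmb6 (at least 40.8-fold, adjusted p = 2.04e-81, 1 of 36), the lysosomal protease Ctsc (at least 20.6-fold, 19 of 36) and Abhd16a (at least 12.9-fold, 3 of 36). The clock-related repressor Bhlhe40 (12.5-fold) and the Fc receptor chain Fcer1g (at least 8.72-fold, 0 of 36) were lower too. By the rule for naming, all 12 had the same sign in 6 of 6 sex-diet groups. Of 7839 probes past the threshold (64.5%), 4199 were higher and 3640 lower in DBA2/J, with 475 and 774 at least 1.5-fold. Of these 4685 (59.8%) had the same sign in all 6 groups, while 4381 passed of the probes above background on all arrays. Of 200 other probes of genes with a 2-fold strain difference, 77% were called in the same direction, 11.5% were called in the opposite one and the rest were not called. For 40% CR the first 2 shares were 93.5% and 0% of 215. Of genes set as strain checks, Hc, complement C5, was 9.19-fold lower in DBA2/J (log2 -3.20 ± 0.07), Glo1 1.7-fold higher (log2 0.77 ± 0.05) and Gpnmb lower by -0.32 ± 0.14 (adjusted p = 0.0421, 4 of 6 groups), which did not pass without the 4 arrays (-0.25), with array weights (-0.24), with the runs of 8 columns (-0.32) or without the detection filter. The 3 probes of Nnt were above background on 0 of 72 arrays.

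Proteasome subunits were lower in DBA2/J in 18 of 27 and higher in 1 (list adjusted p = 2.13e-05, adjusted p = 0.922 with an estimated correlation), with Psmb5 at 4.19-fold and Psma4 at 1.66-fold. Acute phase genes were higher in 22 of 25 and lower in 0 (23 and 0 adjusted over the list alone, 3.27e-05, adjusted p = 0.922 with an estimated correlation). Serum amyloid P, Apcs, stood at 7.81-fold, Serpina3n at 2.81-fold and fibrinogen Fga at 1.73-fold. Glutathione genes were lower in 20 of 27 and higher in 2 (20 and 3 adjusted over the list alone, 0.000566, adjusted p = 0.922 with an estimated correlation). Gsta2 stood at 3.94-fold, Gclm at 1.84-fold and Mgst1 at 1.69-fold. Fatty acid oxidation genes were lower in 21 of 30 and higher in 1 (21 and 2 adjusted over the list alone, 0.00218, adjusted p = 0.995 with an estimated correlation). Ppara itself was at least 3.02-fold lower (above background in 1 of 36 DBA2/J and 36 of 36 C57BL/6J mice), Eci2 1.96-fold and Hadhb 1.9-fold. Sequence differences between the strains under probes, taken up below, may contribute to such values. For Ppara, the proteasome subunit Psmb6 and other single genes this was not tested. Lipogenesis genes were lower in 11 of 19 and higher in 0 (0.0377, adjusted p = 0.995 with an estimated correlation), with Acaca at 3-fold, Me1 at 2.4-fold and Scd1 at 2.09-fold. This list did not pass on the authors' z-scores (0.176). The 5 lists had the same direction under both other scalings, and 84 of 100 splits gave at least 5, so chance could not be excluded for that number.

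Differences between groups in the diet effect were tested directly, as males minus females and DBA2/J minus C57BL/6J. At 40% CR the male-biased list differed between the sexes in 14 of 22 genes, all with the lower change in males (16 adjusted over the list alone, list adjusted p = 1.23e-14, adjusted p = 0.0891 with an estimated correlation). Gstp2 (difference -3.15 ± 0.32, adjusted p = 2.14e-10) changed by -5.04 in DBA2/J males and -1.22 in C57BL/6J males, against -0.07 and 0.11 in females. The difference of Mup21 (-3.80 ± 0.58) was larger. That of Cyp4a12a was fitted at -3.71 ± 0.61, but the gene was above background in few females, where a fall could hardly be seen. Slc22a26 (2.43 ± 0.47), Cyp2b13 (2.52 ± 0.65) and A1bg (3.05 ± 0.66) changed more upward in males. A1bg was above background in few males, so the size of its difference is not settled either. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 2.70 ± 0.56, with 1.69 and 1.62 in C57BL/6J and DBA2/J males and -1.21 and -0.87 in the females. The female-biased list had 5 of 11 genes up in this difference (6 adjusted over the list alone, 0.000418, adjusted p = 0.261 with an estimated correlation). Fatty acid oxidation genes had 11 of 30 down and 1 up (0.000356, adjusted p = 0.819 with an estimated correlation). Heat shock genes had 7 of 14 down and 1 up (8 and 1 adjusted over the list alone, 0.00613, adjusted p = 0.619 with an estimated correlation), and oxidative phosphorylation genes 18 of 66 down and 4 up (21 and 5 adjusted over the list alone, 0.012, adjusted p = 0.819 with an estimated correlation). Without the 4 arrays that stood apart the fatty acid oxidation (0.119) and oxidative phosphorylation lists (0.224) did not pass, so these calls depend on those arrays. In fatty acid oxidation genes, array 5 of the C57BL/6J AL females, array 4 of the DBA2/J AL females and array 106 of the C57BL/6J males at 40% CR lay below their groups by 1.52, 0.53 and 0.85 (log2). In total 1577 probes differed, 847 of them up (53.7%, but 69.7% on the authors' z-scores), and 2445 with array weights.

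Between the strains at 40% CR, Serpina1e differed by 5.24 ± 0.53 (adjusted p = 5.18e-11). It changed by -3.80 and -5.83 in C57BL/6J females and males and by 0.43 in both sexes of DBA2/J. The adipokine gene Serpina12 (3.94 ± 0.38), Mup2 (4.19 ± 0.74) and Mup6 (3.43 ± 0.66) had the same direction. By contrast the neutrophil genes S100a8 (-3.09 ± 0.64), S100a9 (-2.60 ± 0.62) and Retnlg (-2.33 ± 0.52) and the acute phase gene Orm2 (-2.28 ± 0.58) had lower changes in DBA2/J. S100a8 changed by -3.16 and -2.79 in DBA2/J females and males, against 0.04 and 0.18 in C57BL/6J, whose AL females include array 5 with its high neutrophil markers, while the DBA2/J AL females include array 4 with markers raised by 1.90. Among the DBA2/J AL males the mean of the neutrophil markers was 6.87 on arrays 3, 4 and 13 and 5.19 on the other 3. Of neutrophil markers 3 of 11 had a lower change in DBA2/J (7 adjusted over the list alone, list adjusted p = 1.42e-05, adjusted p = 0.451 with an estimated correlation). Of fatty acid oxidation genes 6 of 30 had a higher one (8 up and 1 down adjusted over the list alone, 1.42e-05, adjusted p = 0.693 with an estimated correlation). Urea cycle genes had 6 of 26 up (7 adjusted over the list alone, 5.78e-05, adjusted p = 0.626 with an estimated correlation). A further 9 lists passed, each with adjusted p of 0.45 or more with an estimated correlation. Of 1059 probes that differed, 49.2% were up, but 67.3% on the authors' z-scores. The count was 1791 with array weights, 584 among the probes above background on all arrays and 853 to 1676 when 1 array was left out, with 1676 reached without array 5 of the C57BL/6J AL females.

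At 20% CR 1385 probes differed between the sexes, 779 up (831 in all among the probes above background on all arrays), with A1bg (2.66 ± 0.66), Mup2 (2.33 ± 0.74), Cyp7a1 (2.13 ± 0.56) and the steroid dehydrogenase Hsd17b6 (1.93 ± 0.38) up in males relative to females. Down were Cxcl1 (-2.42 ± 0.78), Mup21 (-2.14 ± 0.58), Cyp4a12a (-1.80 ± 0.61) and the elongase Elovl3 (-1.68 ± 0.36). Between the strains 956 differed, 527 up (55.1%, but 69.3% on the authors' z-scores), with Serpina1e at 4.48, Serpina12 at 2.72, Mup2 at 2.26 and Mup6 at 2.22, and Cyp2d9, Gstp2, Cyp4a12b and Rnf138rt1 at -1.44, -1.43, -1.40 and -1.33. Mup2 (sexes) did not pass on the z-scores or without the 4 arrays (2.13), Cyp2d9 (strains) on the z-scores or under quantile normalization (-0.95), Mup2 (strains) with the intensity trend and robust prior (2.26), and Cyp4a12a (sexes) with the runs of 8 columns as a random block (-1.78). Without the detection filter Mup2, Cxcl1 and Cyp4a12a (sexes) and Mup2, Mup6 and Cyp4a12b (strains) did not pass. In these comparisons of effects the values of A1bg, Cyp4a12a, Cyp4a12b, Serpina12, Elovl3, Rnf138rt1 and Nat8 rest partly on groups above background on no array, so their size is not settled. The strain count was 1573 with array weights, 1439 without the 4 arrays that stood apart and 503 among the probes above background on all arrays. The sex difference itself varied by strain for 1627 probes, 829 up (2714 in all with array weights, 1004 among the probes above background on all arrays). The male minus female difference was higher in DBA2/J for Mup2 (3.07), A1bg (3.02), the hepcidin gene Hamp2 (2.93) and Gstp2 (2.34), and lower for Nat8 (-2.08), Cyp2d9 (-1.98), Depp1 (-1.86) and Wfdc2 (-1.57). Of oxidative phosphorylation genes 14 of 66 had a difference that was up and 2 down (15 and 3 adjusted over the list alone, list adjusted p = 0.00106, adjusted p = 0.982 with an estimated correlation).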

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

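The tests of explanations for the fall of the immune genes and the analyses without the 4 or the 7 arrays were chosen after the results were seen.

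Each array was compared with the other 5 of its group for its correlation with them, its mean level of each cell type list and its level of marker genes. In 25 of 228 groups of values 1 array lay far from the rest, where chance gives about 1 in 20, or 11.4. Array 5 of the C57BL/6J AL females had a correlation of 0.917 (next array 0.978) and mean log2 marker levels of 9.192 for neutrophils (next 5.793), 7.641 for B cells (5.264), 9.016 for Kupffer cells (7.698), 6.666 for T and NK cells (4.954), 7.616 for stellate cells (6.908), 7.228 for endothelium (6.876) and 5.447 for adipocytes (7.059). Array 64 of the DBA2/J females at 20% CR had a correlation of 0.944 (next 0.977), with B cell markers at 7.124 (4.693), T and NK cell markers at 6.245 (4.915), hepatocyte markers at 11.878 (12.081), exocrine pancreas markers at 5.007 (5.393) and Hc at 5.464 (6.251). Array 106 of the C57BL/6J males at 40% CR had a correlation of 0.954 (next 0.982), adipocyte markers at 5.512 (6.97) and Glo1 at 10.631 (10.997). Array 4 of the DBA2/J AL females had a correlation of 0.968 (next 0.98) and neutrophil markers at 8.643 (mean of the other 5, 6.743). Kupffer cell markers were at 8.997 (next 7.064) on array 55 of the DBA2/J males at 20% CR. Neutrophil markers were at 5.39 (next 5.034) on array 110 of the DBA2/J females at 40% CR and at 5.137 (5.577) on 1 array of the C57BL/6J males at 40% CR. Stellate cell markers were at 7.21 (6.731) on array 104 of the DBA2/J females at 40% CR, cholangiocyte markers at 4.322 (4.536) on array 108 of the DBA2/J males at 40% CR, and exocrine pancreas markers at 8.099 (5.545) on 1 array of the DBA2/J females at 40% CR and 6.514 (5.884) on array 8 of the C57BL/6J AL males.

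The response to diet differed between groups by the test of the difference itself. Between the sexes at 40% CR (males minus females) 1577 probes differed, with A1bg at 3.05, Cyp7a1 at 2.70, Cyp2b13 at 2.52, Slc22a26 at 2.43, Mup21 at -3.80, Cyp4a12a at -3.71, Gstp2 at -3.15 and Cyp4a12b at -2.59 (log2). Between the strains at 40% CR (DBA2/J minus C57BL/6J) 1059 differed, with Serpina1e at 5.24, Mup2 at 4.19, Serpina12 at 3.94, Mup6 at 3.43, S100a8 at -3.09, S100a9 at -2.60, Retnlg at -2.33 and Orm2 at -2.28. At 20% CR 1385 differed between the sexes, with A1bg at 2.66, Mup2 at 2.33, Cyp7a1 at 2.13, Hsd17b6 at 1.93, Cxcl1 at -2.42, Mup21 at -2.14, Cyp4a12a at -1.80 and Elovl3 at -1.68. The strains differed at 20% CR for 956, with Serpina1e at 4.48, Serpina12 at 2.72, Mup2 at 2.26, Mup6 at 2.22, Cyp2d9 at -1.44, Gstp2 at -1.43, Cyp4a12b at -1.40 and Rnf138rt1 at -1.33. The sex difference varied by strain for 1627, with Mup2 at 3.07, A1bg at 3.02, Hamp2 at 2.93, Gstp2 at 2.34, Nat8 at -2.08, Cyp2d9 at -1.98, Depp1 at -1.86 and Wfdc2 at -1.57. Leaving out array 5 of the C57BL/6J AL females raised the strain count at 40% CR from 1059 to 1676.

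Interferon, antigen presentation, Kupffer cell, neutrophil and B cell genes fell together at 40% CR. A smaller share of every cell type other than hepatocytes would lower all their markers alike, but the Kupffer cell markers fell further than those of endothelium (difference in mean log2 change -0.422 ± 0.130, or -0.813 ± 0.165 with only the 9 and 11 markers above background on all 72 arrays). The 4 arrays that stood apart were not the whole source either, since 5 of these 5 lists passed without them, although 0 of 40 lists passed with an estimated correlation on all arrays. Part of the fall lay in 3 of the 6 DBA2/J AL males (arrays 3, 4 and 13), and without all 7 arrays 5 of 5 list means still fell by more than 2 SE (Kupffer -0.345 ± 0.125, neutrophil -0.413 ± 0.105), with the gap to endothelium at -0.235 ± 0.114 and the neutrophil list not past the threshold (adjusted p = 0.0693). Fewer Kupffer cells and leukocytes, a loss that Kupffer and stellate cells share (their markers differed by -0.206 ± 0.131, but by -0.615 ± 0.147 above background on all arrays, which argues against an equal loss), or less of these transcripts per cell may each lower the genes, and these stay open.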

How the results depend on the processing

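The setting without the 4 arrays that stood apart, the runs of 8 columns as a block and the overlap with AL arrays split by column number were added after the data were seen, as was the use of z-scores for the replicate block and for leaving out the sample with 2 strain entries, while the other settings had been set beforehand. Among named genes 0 values reversed, with 179 values compared under most settings, 74 with only probes detected on all 72 arrays, 24 in the fit of only 12 arrays and 12 with the fixed block of 8 columns. Most were named for large changes in the main fit on the same arrays, so a reversal was unlikely in advance. The 18 counts of probes stayed within 1.5 times their first value under quantile normalization (942 to 7828), on the authors' z-scores (796 to 7526), without the detection filter (778 to 9406), with an intensity trend and robust prior (936 to 7837), with the replicate number as a block (816 to 7542), with the runs of 8 columns as a random block (859 to 7594) and without the sample with 2 strain entries (788 to 7526). Samples of different groups with the same replicate number had a mean residual correlation of 0.031 over 396 pairs, with a lowest of -0.496. The mean for other numbers was -0.003, and 20 of 72 samples correlated best with their own number. No share expected by chance was computed, so a weak link between samples with the same number stays open. Limited to the 6362 probes above background on all 72 arrays, 10 counts were lower because fewer probes were tested. These were 4148 for 40% CR, 3737 for 20% CR, 2976 for sex, 4381 for strain, 3117 and 2730 for 40% and 20% CR in DBA2/J males, 584 for the strain difference at 40% CR, 831 and 503 for the sex and strain differences at 20% CR and 1004 for the difference of the sex difference between strains. Array weights (0.161 to 2.234) gave higher counts for 4 differences, 2445 (sex) and 1791 (strain) at 40% CR, 1573 (strain) at 20% CR and 2714 (sex by strain), and the cause was not tested. Without the 4 arrays the strain difference at 20% CR had 1439 calls, and the cause was not tested. The fit of only 12 arrays gave 1855 for 40% CR in C57BL/6J females, with fewer arrays to estimate the spread. Slides are not named, so no block for slides was run. The fixed block of 8 columns could be fitted for 5 comparisons and gave 702 (40% CR, C57BL/6J males), 1521 (40% CR, DBA2/J females), 724 (20% CR, C57BL/6J females), 1192 (20% CR, C57BL/6J males) and 1536 (20% CR, DBA2/J females), each fewer than without it. The columns are ordered by group, so these runs largely overlap with the groups and leave few arrays to compare diets within a run. The lower counts therefore neither show nor exclude an effect of slides. Group means take up much of any difference between runs. The random block, with a correlation of 0.0166 within runs, thus does not exclude an effect either. Leaving out 1 array at a time moved the strain difference at 40% CR between 853 and 1676, the latter without array 5 of the C57BL/6J AL females. With a correlation estimated for each list, 0 lists passed at 40% CR, 0 at 20% CR, 0 between them, 1 for sex (male-biased genes) and 0 for strain, since the test then allows for genes that vary together. The overlap of the 20% and 40% CR calls was 3138 on the z-scores with 3 AL mice per group for each diet, with fewer AL arrays in each comparison, against 3683 on the normalized signals with AL arrays split by column number, and the part due to the scale was not tested. Signal over background limits which genes were seen, since 12150 of 25697 probes were above it on at least 6 arrays, and the offset draws folds at probes near background toward no change.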

Other observations

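The tests of fatty acid oxidation and of the strain differences in this part were chosen after the results were seen. The counts over other splits of the arrays were set before the data were examined.

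Several gene groups did not pass as lists at 40% CR although single members changed. Of 14 NAD and sirtuin genes 7 rose and 4 fell (8 and 4 adjusted over the list alone, list adjusted p = 0.106). Nampt, which makes the NAD precursor NMN, rose 2.08-fold (log2 1.06 ± 0.08) and the mitochondrial deacetylase Sirt3 by 0.72 ± 0.06, while Parp1 changed by -0.70 ± 0.07. The insulin and IGF list had 8 of 16 up and 2 down (adjusted p = 0.223), with the binding proteins Igfbp1 at 1.29 ± 0.20 and Igfbp2 at 1.23 ± 0.16 and Igf1 at -0.35 ± 0.05. In the senescence and p53 list 6 of 13 fell and 2 rose (adjusted p = 0.158), with the cell cycle inhibitor Cdkn1a at -1.36 ± 0.25 and Gadd45a at -1.01 ± 0.20. Autophagy and lysosome genes had 8 of 24 up and 5 down (8 and 4 adjusted over the list alone, adjusted p = 0.248), with Map1lc3b at 0.72 ± 0.09. Bile acid genes had 9 of 18 up and 3 down (adjusted p = 0.157), with the transporter Slco1a4 at 2.09 ± 0.14 and Hsd3b7 at -1.36 ± 0.09. These genes and those of the next paragraph were chosen after their values were seen.

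Of 27 glutathione and Nrf2 genes 15 rose and 6 fell (16 and 6 adjusted over the list alone, adjusted p = 0.158), with Gstt2 at 1.14 ± 0.14, and of 18 antioxidant enzymes 8 rose and 4 fell (8 and 5 adjusted over the list alone, adjusted p = 0.51), with Glrx at 0.72 ± 0.06 and Prdx4 at -0.54 ± 0.07. Heat shock genes had 6 of 14 up and 2 down (6 and 3 adjusted over the list alone, adjusted p = 0.158), with the mitochondrial chaperonin Hspd1 at 0.66 ± 0.05 and Fkbp4 at -0.83 ± 0.10. One-carbon and methionine genes had 9 of 18 up and 4 down (adjusted p = 0.397), with Mat1a at 0.70 ± 0.07 and Cbs at -0.92 ± 0.07, and iron and heme genes 5 of 13 up and 2 down (6 and 2 adjusted over the list alone, adjusted p = 0.302), with Alas1, the first enzyme of heme synthesis, at 1.15 ± 0.11. The control list of sex chromosome genes had 3 of 8 up and 0 down (adjusted p = 0.179), with the X-linked Ddx3x at 0.70 ± 0.07.

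Fatty acid oxidation genes rose under both diets. A larger share of hepatocytes was excluded as the whole source, because their mean rose by 0.822 ± 0.103 more than that of the hepatocyte markers. A longer time since the last meal in CR mice is a candidate explanation, as AL mice ate until they were killed. If that time acts alike at both levels of CR it predicts a like rise. In DBA2/J females the mean at 40% CR exceeded that at 20% CR by 0.656 ± 0.215 (0.544 ± 0.185 without the 4 arrays), which argues against a like rise there. That group was singled out after the values were seen, and over all 4 groups the difference was 0.045 ± 0.108. A like time since the meal need not act alike at both levels, so it stays open in DBA2/J females too. In the other 3 strain-sex groups the difference was -0.159 ± 0.124 after a rise of 1.073 ± 0.124 from AL to 20% CR, and there the time since the meal and an effect of restriction complete at 20% CR both stay open.

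Of the 12 largest strain differences named, 8 rested on a single tested probe. Sequence differences between the strains under the probes may contribute, since the other probes of a gene were called in the same direction as a 2-fold strain difference in 77% of 200 cases (SE 4) and in the opposite one in 11.5%, against 93.5% (SE 2.8) and 0% for 40% CR. These shares show that some strain calls depended on the probe. Their gap is not clear, by 2 SE, of the 10 points set for it after the results were seen. For the genes with several probes, taken as a set, the shares therefore do not tell sequence differences and real differences in expression apart. Genes with a single tested probe allow no such comparison. Weaker binding of DBA2/J RNA to probes made for the C57BL/6J sequence is consistent with the direction, as 66.7% of the 4-fold differences (62 of 93, 95% exact interval 56.1% to 76.1%) were lower in DBA2/J, but the share did not grow with the size of the difference (64.2% at 2-fold and 61.8% at 8-fold, interval 43.6% to 77.8%). A real difference of expression between the strains remains open too and, beyond the comparison of probes of the same gene, was not tested.

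For each comparison 100 splits of the same arrays into groups of the same sizes were counted, the real one included. Differences of effects apart, chance was excluded as the source of the number of probes where only 1 of 100, the real split, reached it. This held for 40% CR (6875, highest other 321), 20% CR (5916, 203), 40% against 20% CR (1725, 1), sex (5146, 384) and strain (7839, 2902). It held for 40% CR in C57BL/6J females (2821, 1015) and males (3171, 1026) and in DBA2/J females (3725, 1401) and males (5204, 3267), and for 20% CR in C57BL/6J females (3115, 1365) and males (2033, 700) and in DBA2/J females (2461, 1485) and males (4479, 2485). Only the real split reached the sex difference (1577, 203) and the strain difference (1059, 932) at 40% CR, and the difference of the sex difference between strains (1627, 26). At 20% CR 2 of 100 splits reached the sex difference (1385, 1628) and the strain difference (956, 1033). For these differences of effects the splits cannot exclude chance. They mix the diets or the sexes within groups, which removes the average effect as well and adds it to the spread. The number of lists past the threshold at 40% CR was reached by 3 of 100 splits, the real one included (23, highest other 24). Another split gave more lists, so chance is less likely there but was not excluded. Nor could chance be excluded for the number of lists at 20% CR (18, highest other 24, 11 of 100), for 40% against 20% CR (6, 20, 72 of 100), for sex (10, 22, 44 of 100) or for strain (5, 22, 84 of 100). The median of the other splits was 10 lists at 40% and 20% CR and 8 in the other 3 comparisons, so single lists often pass in splits other than the real one. Such splits can keep part of a real effect, so these medians are not rates without any effect.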
